A study of Homo sapiens with 43 samples.

How the data were processed

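RNA sequencing was done on total RNA from 2 human cancer cell lines, H2087 and HCC1954, and from their latency-competent cell derivatives (LCC), per the labels. Cells were grown for 48 h below confluence in mitogen-rich medium (MRM) or mitogen-low medium (MLM). The series lists 43 samples, of which 31 are RNA and 12 are chromatin immunoprecipitation or input samples. The 12 chromatin samples were not analysed here. The remaining 30 RNA libraries with values fall into 4 tables, and H2087 parental library 3 in MLM, which the labels list, has no column. In H2087 each medium has 6 LCC libraries, 1 from each of 6 derivatives per the labels, and 2 parental libraries. In HCC1954 each medium has 3 parental libraries and 4 LCC libraries, 2 from each of the derivatives LCC1 and LCC2. Nothing in the labels says that replicates are separate cultures, so the p-values measure the spread between these samples.

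The deposited tables hold 1 normalized signal value per gene and library, per the file headers. The submitters' processing notes name Bowtie2 2.2.4, HTSeq 0.6.1p1, DESeq2 1.8.1, HOMER 4.2, R 3.1.2, SAMtools and the builds hg19 and GRCh37, without their role or order. The unit was read from the deposited signal values themselves. Every value of a library was a whole multiple of 1 step per library, within a tolerance of 0.01 reads, in 100% of the values. The deposited values are therefore read counts divided by a size factor, and the counts were recovered by multiplying them back. Size factors by the median-of-ratios method, recomputed over both media of a line together, differed from the recovered ones by at most 7.43e-11 in H2087 and 5.57e-11 in HCC1954. Recomputed within 1 medium they differed by up to 0.874 and 0.26. Both tables of a line thus share 1 normalization, which the design had not assumed: it had planned levels in both media without a test. Tests between media were therefore added after the files were seen.

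Depth ran from 12131848 to 55653300 reads per library in H2087 and from 24852118 to 44705518 in HCC1954. Where a group of libraries holds 1 to 3 reads of a gene, its ratio is given with an exact 95% counting interval in place of the fitted fold change. Such intervals cover counting error only, since reads without molecular identifiers are not independent molecules. Mean values are deposited normalized counts, or CPM (the recovered reads scaled to equal library totals) where so marked.

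In each line and medium LCC libraries were compared with parental libraries on log2 of the deposited value plus 1, with limma 3.58.1 (trended prior variance, two-sided) in R 4.3.3. Genes with a mean value of at least 10 were tested, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are log2 of LCC minus parental with their standard error. The difference of the LCC effect between the media and the contrast of LCC2 with LCC1 used the same method. Media were compared within each cell type with edgeR 4.0.16 (quasi-likelihood, two-sided) on the recovered reads. Calls shared between comparisons were tested with Fisher's exact test, one-sided for excess, and set beside the number expected for independent lists. Adjusted p-values in the text come from limma for LCC against parental and from edgeR for the media.

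A set of 32 gene lists was fixed before the data were examined: cell cycle and DNA replication, CDK inhibitors and quiescence, WNT inhibitors, WNT targets, WNT ligands and receptors, SOX factors and stem cell regulators, ligands that activate natural killer (NK) cells, death receptors, MHC class I and antigen processing, interferon stimulated genes, NF-kB cytokines and chemokines, epithelial markers, basal and squamous keratins, mesenchymal and epithelial-mesenchymal transition (EMT) genes, TGF-beta and BMP pathway, Notch pathway, MAPK targets, cholesterol and fatty acid synthesis, glycolysis and hypoxia, integrated stress and unfolded protein response, heat shock, integrins and adhesion, serpins and plasminogen activation, lung identity, ERBB2 and breast identity, markers of fibroblasts, blood, endothelium and kidney, ribosomal proteins, mitochondrially encoded genes and histone genes. Each list with at least 3 tested members was tested with camera in limma at a preset correlation of 0.01 and again with an estimated correlation. The mitochondrially encoded list had 0 tested members in every table. The genes named in the text follow a rule also fixed beforehand. It takes up to 6 genes per direction with the largest change among called genes with a mean of at least 100 and every LCC library on 1 side of every parental library, up to 4 called members of a list that is called or has at least 3 called members, 18 focal genes, 6 genes per direction called in all 4 comparisons, and 4 per direction for each difference between media and between derivatives. A subset of the genes so chosen is printed.

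Genes were placed in their order along the chromosomes with a table of assembly GRCh38.p14, while the files use hg19 and GRCh37, so this table served only for names and neighbourhood and no coordinates are given. Runs of neighbouring genes that shift together were sought as stretches of at least 8 genes with a running median over 31 genes beyond 0.5 in log2, among genes with a mean of at least 50, against 100 permuted gene orders. Gene names known to the reference were 99.9% of those in H2087 and 95.5% of those in HCC1954. Strand use in counting is not stated, so reads of overlapping or antisense genes cannot be told apart, and neither can reads shared by near-identical copies such as ULBP, HLA, histone or ribosomal genes.

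Samples with the same number were checked for pairing by correlating their deviations from the group means across genes. The 6 H2087 LCC derivatives correlated with themselves across the media at 0.41 to 0.76 and the 4 HCC1954 LCC libraries at 0.51 to 0.7, so LCC libraries pair by derivative. The reported tests between media and of the difference of the LCC effect used group means and left this pairing out. A block of same-named libraries was run only as an alternative. Of the 4 HCC1954 LCC libraries of MLM, 3 matched the library of the same name in MRM best and LCC1 library 2 matched LCC1 library 1, so a block of same-named libraries pairs them only in part. H2087 LCC6 is an exception, since in MRM it correlated better with LCC5 of MLM (0.495) than with LCC6 of MLM (0.416). Parental libraries of the same number correlated at 0.02 to 0.12 across the media, and libraries of the same number within 1 HCC1954 table at -0.08 to 0.05. No 2 of the 50 pairs of libraries within groups were duplicates, as their lowest chi-square per degree of freedom was 1.9.

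limma and camera were tested on reads simulated with the depth and means of these libraries, each gene drawn independently. limma recovered 90% of 50 genes changed 4-fold in H2087 in MLM, 90% in MRM, 88% in HCC1954 in MLM and 86% in MRM. Of 50 genes changed 2-fold it recovered 62%, 42%, 50% and 44%, and of the calls 5.07%, 2.56%, 4.84% and 6.56% were false. Libraries too were drawn independently, with the same spread in parental and LCC groups and no structure by derivative. These shares of false calls thus do not cover unequal spread or libraries that cluster by derivative. camera called the raised list in each and 0 of 30 unchanged lists. Real lists can be correlated (an estimated 0.892 for interferon stimulated genes of HCC1954 in MLM), so this does not measure false calls among such lists. The search for runs was tested on 9000 simulated genes with independent normal noise, without the depth and means of these libraries. It found 90% of 180 inserted genes and 0 outside. Alternatives tried were other pseudocounts (0.5 and 5), no filter and a minimum mean of 50, scaling by library total or TMM, edgeR and DESeq2 1.42.0 on the recovered reads, limma without a trend, weights per library, a spread shared over both tables of a line, blocks by library number, HCC1954 derivatives averaged or alone, a minimum log2 fold change of 1, fry and an estimated correlation for the lists, and each library left out in turn.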

Results

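Gene expression was measured by RNA sequencing in H2087, an established lung cancer line, and HCC1954, a breast cancer line with an amplified ERBB2 gene. Each line was studied as the parental cells and as latency-competent derivatives, in mitogen-low and mitogen-rich medium. In MLM the 6 H2087 LCC libraries held a mean of 48.7 M reads and the 2 parental ones 53.1 M. In MRM the 6 LCC libraries held 18.1 M and the 2 parental ones 15.1 M. The 4 HCC1954 LCC and 3 parental libraries held 26.0 and 25.5 M reads in MLM and 34.4 and 38.6 M in MRM, so medium and depth move together. The comparisons ask how the latency-competent cells differ from the parental cells in each medium, and how both differ between the media. List counts give members called higher, lower and not called, out of those tested. For every gene named below as higher or lower in LCC cells, each LCC library lay on that side of each parental library.

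In MLM, several genes were strongly lower in H2087 LCC cells than in parental cells (6 against 2 libraries). QPRT, an enzyme of NAD synthesis, stood at a log2 fold change of -8.00 ± 0.95 (SE), the fatty acid elongase ELOVL2 at -7.33 ± 0.91 and PPP2R2C, a regulatory subunit of a protein phosphatase, at -7.31 ± 0.54. The guidance cue SEMA3C was lower at -6.39 ± 1.36 and CCL2, a chemokine that attracts monocytes, at -5.52 ± 1.49, with adjusted p = 0.0196 and 0.0446 in limma. Without LCC6, SEMA3C stood at -5.63, and without LCC3, CCL2 stood at -4.88. Both lost their call without either parental library, and CCL2 also without LCC5 or LCC6. Higher genes included KRT75, a keratin of hair follicles (3.15 ± 0.61), the membrane-bound chemokine CX3CL1 (2.35 ± 0.41), the growth factor FGF1 (2.06 ± 0.34) and COL8A1, a collagen chain (1.73 ± 0.37). SOX9, a transcription factor of progenitor cells, rose by 0.96 ± 0.16 (adjusted p = 0.00809), from a mean of 1481 to 2904 normalized counts.

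H2087 NF-kB cytokines and chemokines in MLM had 0 higher, 6 lower and 16 not called of 22 (0 and 7 adjusted over the list alone, camera adjusted p = 0.111). The lower members were led by BIRC3, an inhibitor of apoptosis (-3.32 ± 0.47), the NF-kB subunit NFKB2 (-1.27 ± 0.14), the cytokine IL6 (-2.12 ± 0.54) and the NF-kB inhibitor NFKBIA (-0.94 ± 0.20). Mesenchymal and EMT genes stood at 5 higher, 0 lower and 13 not called of 18 (5 and 0 adjusted over the list alone, camera adjusted p = 0.0187 with a preset correlation and adjusted p = 0.757 with an estimated correlation). The matrix protein TNC rose by 0.78 ± 0.08, the matricellular protein CTGF by 0.98 ± 0.20, TGFBI by 0.93 ± 0.22 and the receptor kinase AXL by 0.85 ± 0.21. CDK inhibitors and quiescence genes had 4 higher, 0 lower and 20 not called of 24 (9 and 1 adjusted over the list alone, camera adjusted p = 0.0174 with a preset correlation and adjusted p = 0.757 with an estimated correlation). CDKN2B, an inhibitor of cyclin-dependent kinases, was higher by 1.21 ± 0.27, the atypical cyclin CCNG2 by 0.93 ± 0.18 and the retinoblastoma relative RBL2 by 0.37 ± 0.07. Integrins, laminins and adhesion genes had 3 higher, 0 lower and 23 not called of 26 (3 and 0 adjusted over the list alone, camera adjusted p = 0.0187 with a preset correlation and adjusted p = 0.404 with an estimated correlation). Higher members were MCAM, an adhesion molecule first described in melanoma (1.02 ± 0.13), and the integrin ITGA3 (0.60 ± 0.12). MAPK targets showed 3 higher, 2 lower and 25 not called of 30 (3 and 2 adjusted over the list alone, camera adjusted p = 0.0431 with a preset correlation and adjusted p = 0.416 with an estimated correlation). The ERK phosphatase DUSP6 rose by 0.89 ± 0.20 and the ETS factor ETV5 by 0.66 ± 0.12, while MYC was lower at -0.48 ± 0.09.

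Other lists moved in few members. The Notch pathway had 1 higher, 5 lower and 12 not called of 18 (5 and 5 adjusted over the list alone, camera adjusted p = 0.892). The regulator HES6 was lower at -1.77 ± 0.17 and the ligand JAG2 at -1.68 ± 0.35. The TGF-beta and BMP pathway held 1 higher, 3 lower and 24 not called of 28 (1 and 3 adjusted over the list alone, camera adjusted p = 0.745). The ligands BMP6 (-5.38 ± 0.40) and BMP7 (-6.60 ± 0.71) were lower. WNT ligands and receptors counted 2 higher, 2 lower and 17 not called of 21 (3 and 2 adjusted over the list alone, camera adjusted p = 0.745). The ligand WNT5B was lower at -6.34 ± 0.65. Heat shock and early stress genes had 0 higher, 3 lower and 14 not called of 17 (0 and 3 adjusted over the list alone, camera adjusted p = 0.253). The heme-degrading enzyme HMOX1 was lower at -1.69 ± 0.23. Cell cycle genes gave 1 higher, 0 lower and 39 not called of 40 (0 and 0 adjusted over the list alone, camera adjusted p = 0.13). The proliferation marker MKI67 was not called (0.17 ± 0.07, adjusted p = 0.166), nor were SOX2, a stem cell factor (1.01 ± 0.69, adjusted p = 0.371), and DKK1, a secreted WNT inhibitor (-0.81 ± 0.46, adjusted p = 0.282). For interferon stimulated genes, limma gave 0 higher, 0 lower and 34 not called of 34 (0 and 0 adjusted over the list alone, camera adjusted p = 0.892). Lung identity genes gave 0 higher, 1 lower and 12 not called of 13 (0 and 1 adjusted over the list alone, camera adjusted p = 0.892). Serpins and plasminogen activation had 3 higher, 0 lower and 14 not called of 17 (3 and 0 adjusted over the list alone, camera adjusted p = 0.0605).

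In H2087 in MLM, limma called 616 genes higher and 1095 lower in LCC cells of 12480 tested, and scaling to the library total gave 465 and 1579. Groups did not overlap for 36.4% of tested genes, where fully exchangeable libraries would give 7.14%. They were not exchangeable: the parental pair differed by a chi-square per degree of freedom of 2.63, and pairs of derivatives by 52.3 to 156. The share by chance is thus higher than 7.14% and was not computed. The 1711 calls became 139 without parental 1, 113 without parental 2 and 1102 without LCC5.

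In MRM, the H2087 LCC cells expressed genes that were close to silent in the parental cells, again with 6 against 2 libraries. The peptidase MME was higher 342-fold, with a 95% counting interval of 61.3 to 13530, the kainate receptor subunit GRIK2 48.6-fold, with a 95% counting interval of 16.5 to 236, and TCN1, a cobalamin-binding protein, 50.8-fold, with a 95% counting interval of 17.3 to 247. The fitted log2 change of MME, which depends on the pseudocount, was 6.96. It stood at 7.65 without parental 1 and 6.28 without parental 2, a spread that the counting interval does not cover. MME lost its call without either parental library. DKK1 rose from a mean of 11.4 to 1005 normalized counts (5.26 ± 1.15, adjusted p = 0.0194), with LCC4 at 4001, the other 5 at 97.6 to 802 and a mean of 406 without LCC4. CRISPLD1 rose by 5.42 ± 1.00. Lower genes included the matrix protease ADAMTS4 (-6.70 ± 0.50), the potassium channel KCNJ12 (-6.42 ± 1.24), CCL2 (-5.59 ± 1.18), the lysosomal GTPase RRAGD (-4.12 ± 0.60) and the netrin receptor UNC5B (-3.93 ± 0.45). The LCC effect differed between media (log2, MLM minus MRM) for MME (-6.62), CRISPLD1 (-6.36), DKK1 (-6.07), GRIK2 (-3.80), ADAMTS4 (7.34) and UNC5B (4.19). Parental libraries of the media also differ in runs of neighbouring genes, whose source stays open. Changes in MRM, here and in the lists below, thus need not be traits of LCC cells.

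SOX factors and stem cell regulators of H2087 in MRM had 6 higher, 2 lower and 12 not called of 20 (9 and 2 adjusted over the list alone, camera adjusted p = 0.154). SOX4 rose by 3.02 ± 0.37, SOX21 by 2.79 ± 0.23, SOX2 by 1.94 ± 0.44 and SOX9 by 1.15 ± 0.11. Cell cycle and DNA replication genes stood at 12 higher, 0 lower and 28 not called of 40 (18 and 0 adjusted over the list alone, camera adjusted p = 1.25e-05 with a preset correlation and adjusted p = 0.5 with an estimated correlation). The replication licensing factor CDC6 rose by 0.80 ± 0.10, the spindle checkpoint kinase BUB1B by 0.79 ± 0.11, the cyclin CCNB2 by 0.49 ± 0.09 and the thymidine kinase TK1 by 0.50 ± 0.10. BUB1B lies in a run of neighbouring genes from GOLGA8A to MAPKBP1 whose median was 0.74 higher in LCC cells, and MKI67 was not called (0.12 ± 0.16, adjusted p = 0.655). Heat shock and early stress genes counted 4 higher, 0 lower and 13 not called of 17 (5 and 0 adjusted over the list alone, camera adjusted p = 0.0305 with a preset correlation and adjusted p = 0.5 with an estimated correlation). The chaperone DNAJB1 stood at 0.96 ± 0.16 and the quinone reductase NQO1 at 0.44 ± 0.09.

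Mesenchymal and EMT genes of H2087 in MRM had 4 higher, 0 lower and 14 not called of 18 (5 and 0 adjusted over the list alone, camera adjusted p = 0.154). The matrix protein FN1 rose by 3.81 ± 0.52, and the mean of the repressor SNAI2 stood at 610.5 against 119.9 normalized counts. TGF-beta and BMP pathway members gave 6 higher, 2 lower and 19 not called of 27 (9 and 2 adjusted over the list alone, camera adjusted p = 0.154). The ligand BMP4 rose by 4.53 ± 0.51 and TGFB2 by 2.00 ± 0.35. Notch pathway genes gave 5 higher, 0 lower and 15 not called of 20 (5 and 0 adjusted over the list alone, camera adjusted p = 0.23). Among these was the receptor NOTCH3 (2.47 ± 0.39). MAPK targets held 6 higher, 1 lower and 23 not called of 30 (6 and 1 adjusted over the list alone, camera adjusted p = 0.0794). The AP-1 subunit FOSL1 stood at 1.25 ± 0.16 and the cyclin CCND1 at 1.27 ± 0.17. Epithelial markers had 3 higher, 0 lower and 21 not called of 24 (3 and 0 adjusted over the list alone, camera adjusted p = 0.057), among them the keratins KRT7 (1.35 ± 0.34) and KRT19 (1.08 ± 0.26). Lung identity genes showed 2 higher, 1 lower and 10 not called of 13 (2 and 1 adjusted over the list alone, camera adjusted p = 0.192). The adhesion molecule CEACAM6 rose by 3.76 ± 0.51. CDK inhibitors and quiescence genes gave 4 higher, 3 lower and 17 not called of 24 (6 and 3 adjusted over the list alone, camera adjusted p = 0.81). TXNIP, an inhibitor of thioredoxin, rose by 2.18 ± 0.19. NF-kB cytokines and chemokines showed 1 higher, 4 lower and 17 not called of 22 (1 and 5 adjusted over the list alone, camera adjusted p = 0.192). The growth factor CSF2 was lower at -1.92 ± 0.31 and the adhesion molecule ICAM1 at -0.98 ± 0.17. Ligands that activate NK cells had 0 higher, 2 lower and 13 not called of 15 (1 and 2 adjusted over the list alone, camera adjusted p = 0.159). ULBP2, a ligand of the NKG2D receptor, was lower at -1.08 ± 0.17 (adjusted p = 0.00627), and the related ULBP1 was not called (-0.88 ± 0.32, adjusted p = 0.101).

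In H2087 in MRM, limma called 1094 genes higher and 728 lower of 12495 tested, with 38% of genes not overlapping between groups. Scaling to the library total gave 828 higher and 1207 lower. The 1822 calls became 141 without parental 1, 213 without parental 2, 1206 without LCC5 and 1507 without LCC6. LCC6 of MRM correlated better with LCC5 of MLM (0.495) than with LCC6 of MLM (0.416), and held 0 genes in runs of neighbours where LCC6 of MLM held 99. Such counts also differed in LCC3 (0 in MLM, 52 in MRM) and LCC5 (31 and 0), but little in LCC2 (167 and 149). The counts alone thus do not set LCC6 apart. The 301 genes in runs that differ between the parental libraries of the media do. Over these genes the deviation of LCC6 of MRM from the other derivatives correlated at 0.412 with the parental difference (MRM minus MLM). All other LCC libraries, LCC6 of MLM (0.059) among them, lay between -0.276 and 0.097. LCC5 and LCC6 of MRM differed by a chi-square per degree of freedom of 6.93 (25.9 to 111 in the other pairs, 55.7 for LCC5 and LCC6 in MLM), so it is in doubt that MRM holds 6 distinct derivatives.

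**Figure D1:**
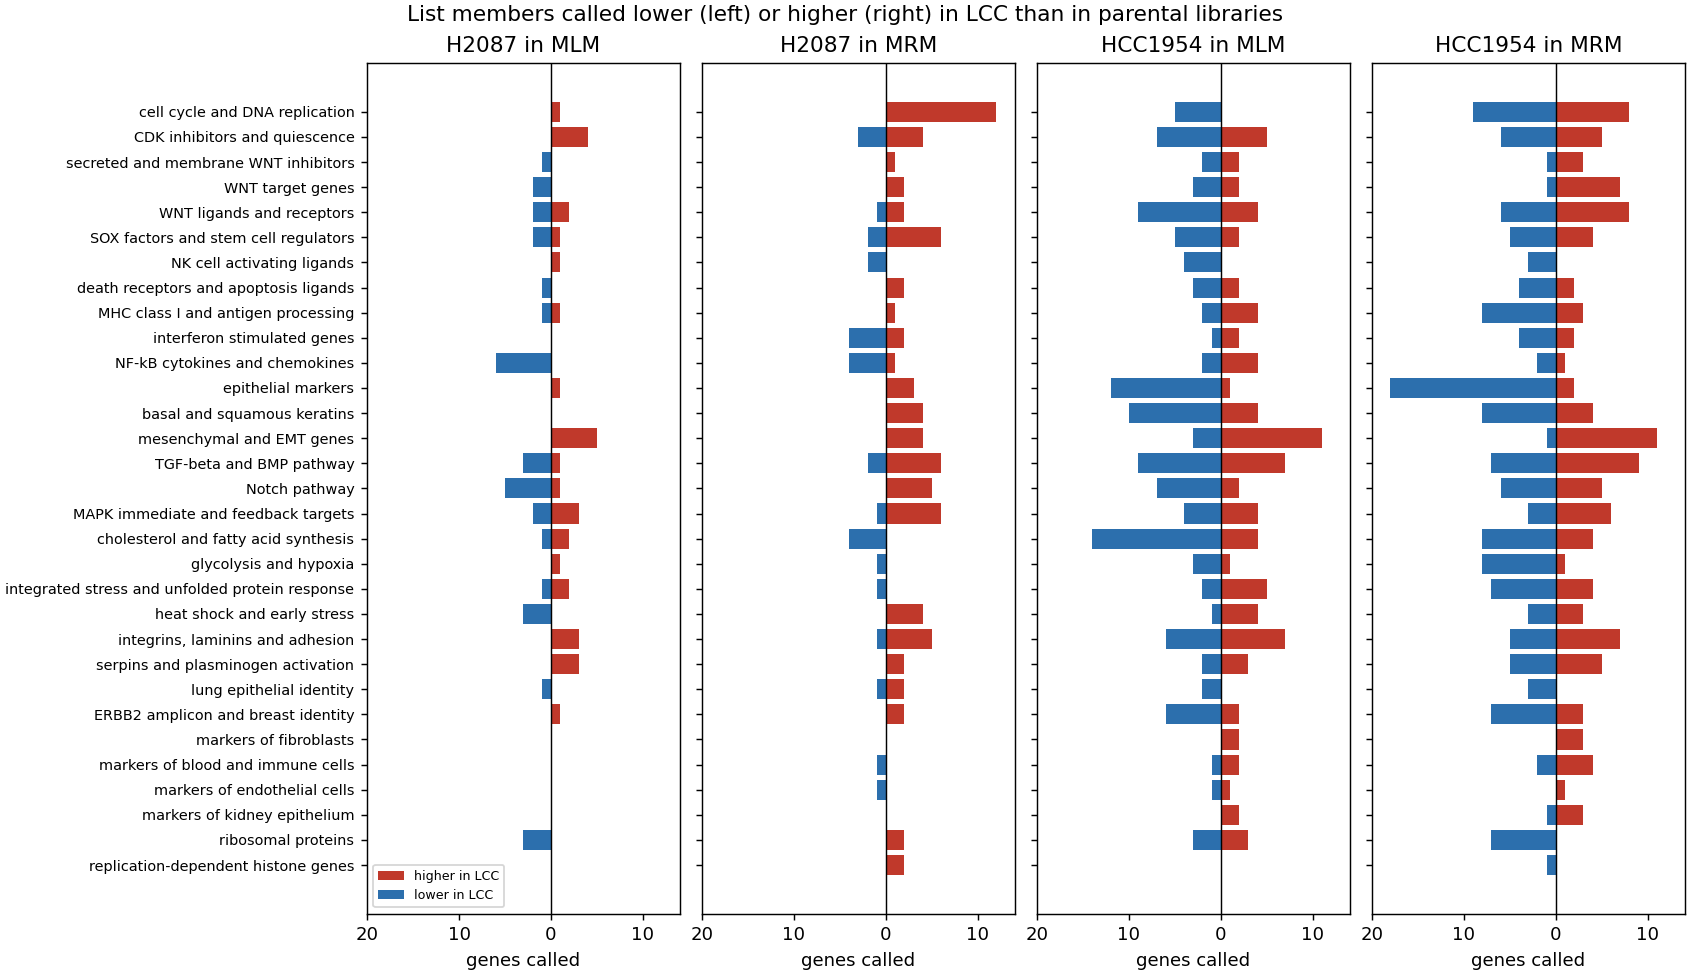
Number of members of each fixed gene list called lower (left) or higher (right) in LCC than in parental cells by limma at adjusted p under 0.05, for both lines and media. Epithelial markers of HCC1954 in MRM have 18 members lower and 2 higher of 24 tested.

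The difference between LCC and parental libraries was not the same in both media for many H2087 genes. ADAMTS4 differed by 7.34 ± 0.76 (MLM minus MRM, adjusted p = 6.86e-05), SH3TC1 by 2.34 ± 0.26 and KIF13B, a kinesin, by 1.34 ± 0.16. On the other side stood ZSCAN18 (-4.78 ± 0.32), CMBL, a hydrolase (-4.28 ± 0.29), BAG4, an inhibitor of death receptor signals (-1.64 ± 0.13), and VDAC3, a mitochondrial channel (-1.44 ± 0.09). DKK1 differed by -6.07 ± 1.35 (adjusted p = 0.011), FN1 by -2.99 ± 0.77 and ULBP2 by 1.38 ± 0.20. Of 31 lists, camera called integrated stress and unfolded protein response (2 members higher, 0 lower, adjusted p = 0.034) and heat shock (0 higher, 2 lower, adjusted p = 0.00364). Neither kept its call, with adjusted p = 0.947 and 0.674 with an estimated correlation. limma called 512 genes higher and 832 lower of 12535, and 3426 with libraries of the same name paired between the media as a block. BAG4, VDAC3 and CMBL lie in runs of neighbouring genes that differ between the parental libraries of the media. Of 301 genes in these runs limma called 99 (32.9%), against 1124 of 10874 (10.3%) outside them. The source of these runs stays open, so a call need not be a response of LCC cells to the medium. ZSCAN18 lies in a run that differs between LCC and parental cells in MRM, from ZFP28 to ZSCAN18, with a median of 0.79. Its mean was 922.5 normalized counts in parental cells in MLM and 30 in MRM, against 938.5 and 886.4 in LCC cells. The 1344 calls became 464 and 655 without parental 1 and 2 of MRM, and 409 and 410 without parental 1 and 2 of MLM.

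HCC1954 LCC cells in MLM (4 libraries against 3 parental) expressed FOXI1, a forkhead factor, 1077-fold, with a 95% counting interval of 368 to 5224, above the parental cells. The chromatin organizer SATB1 was higher 495-fold, with a 95% counting interval of 169 to 2400. LMAN1, a cargo receptor between endoplasmic reticulum and Golgi, was higher in the parental cells 9876-fold, with a 95% counting interval of 1772 to 390200. The palmitoyltransferase ZDHHC2 rose by 7.77 ± 0.56, while the keratin KRT4 stood at -6.92 ± 0.50, the matrix protein MXRA5 at -6.82 ± 0.41 and CCL2 at -6.70 ± 0.81, all lower (adjusted p = 1.64e-04, 1.01e-04 and 0.00102).

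Epithelial markers of HCC1954 in MLM had 1 higher, 12 lower and 11 not called of 24 (1 and 12 adjusted over the list alone, camera adjusted p = 0.00446 with a preset correlation and adjusted p = 0.779 with an estimated correlation). KRT8, a keratin of simple epithelia, was lower at -1.25 ± 0.11, the mucin MUC1 at -1.68 ± 0.15 and the GTPase RAB25 at -1.05 ± 0.11. The adhesion molecules CDH1 and EPCAM stood at -0.76 ± 0.15 and -0.56 ± 0.07. Mesenchymal and EMT genes gave 11 higher, 3 lower and 6 not called of 20 (12 and 3 adjusted over the list alone, camera adjusted p = 0.0737). The EMT factor TWIST1 was higher 347-fold, with a 95% counting interval of 95.7 to 2867, AXL rose by 3.90 ± 0.27, FN1 by 2.98 ± 0.29 and the protease MMP2 by 2.78 ± 0.14. ERBB2 and breast identity genes held 2 higher, 6 lower and 10 not called of 18 (2 and 6 adjusted over the list alone, camera adjusted p = 0.428). The luminal factors SPDEF (-1.55 ± 0.15), GATA3 (-1.04 ± 0.13) and FOXA1 (-0.99 ± 0.09) were lower. GATA3 lies in a run of neighbouring genes, from NET1 to ZNF37A, with a median of -0.93. ERBB2 itself was not called (-0.39 ± 0.18, adjusted p = 0.128).

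Cholesterol and fatty acid synthesis genes of HCC1954 in MLM counted 4 higher, 14 lower and 15 not called of 33 (5 and 14 adjusted over the list alone, camera adjusted p = 0.351). The isomerase IDI1 (-1.10 ± 0.12) and ACLY, which makes acetyl-CoA (-0.80 ± 0.09), were lower. The desaturase FADS1 was higher, at a mean of 2052 against 723 normalized counts. Of these genes 27 of 33 lay lower both in parental 3 than in the other parental libraries and in LCC1 library 2 of MRM than in library 1. WNT ligands and receptors showed 4 higher, 9 lower and 14 not called of 27 (4 and 9 adjusted over the list alone, camera adjusted p = 0.563). The ligand WNT5A was lower at -3.34 ± 0.22 and WLS, which carries WNT ligands to the surface, at -2.14 ± 0.24. DKK1 rose by 0.93 ± 0.30 (adjusted p = 0.0437). SOX factors and stem cell regulators gave 2 higher, 5 lower and 16 not called of 23 (2 and 5 adjusted over the list alone, camera adjusted p = 0.692). SOX9 rose by 0.81 ± 0.11 while SOX2 was lower at -3.45 ± 0.39. MHC class I genes had 4 higher, 2 lower and 14 not called of 20 (4 and 0 adjusted over the list alone, camera adjusted p = 0.692). HLA-B (0.67 ± 0.13) and HLA-F (1.72 ± 0.31), which present peptides or bind NK receptors, rose. NK ligands showed 0 higher, 4 lower and 11 not called of 15 (0 and 4 adjusted over the list alone, camera adjusted p = 0.563). The lower ones include SLAMF7 (-2.52 ± 0.42), ULBP3 (-0.96 ± 0.18) and MICA (-0.49 ± 0.14). Interferon stimulated genes showed 2 higher, 1 lower and 32 not called of 35 (1 and 1 adjusted over the list alone, camera adjusted p = 0.351). Cell cycle genes in this comparison had 0 higher, 5 lower and 35 not called of 40 (0 and 1 adjusted over the list alone, camera adjusted p = 0.351). Parental 3 stood apart from the other parental libraries by a median of -1.08 in interferon genes, -0.31 in MHC class I genes and 0.75 in cell cycle genes. MKI67 was not called (-0.19 ± 0.25, adjusted p = 0.579).

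In HCC1954 in MLM, limma called 2672 genes higher and 2869 lower of 15186. Groups did not overlap for 46.9% of genes, where fully exchangeable libraries would give 5.71%. LCC libraries of 1 derivative differed by a chi-square per degree of freedom of 3.64 and 2.85, and those of different derivatives by 106 to 125. The share by chance is thus higher than 5.71% and was not computed. The 4 LCC libraries, 2 from each of 2 derivatives, counted as 4 replicates, and with libraries of a derivative averaged 2593 genes were called in place of 5541. Scaling to the library total, which moved the median of all genes by 0.11, gave 3350 and 2114. The 5541 calls became 3660 without parental 1 and 5190 without parental 3.

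**Figure D2:**
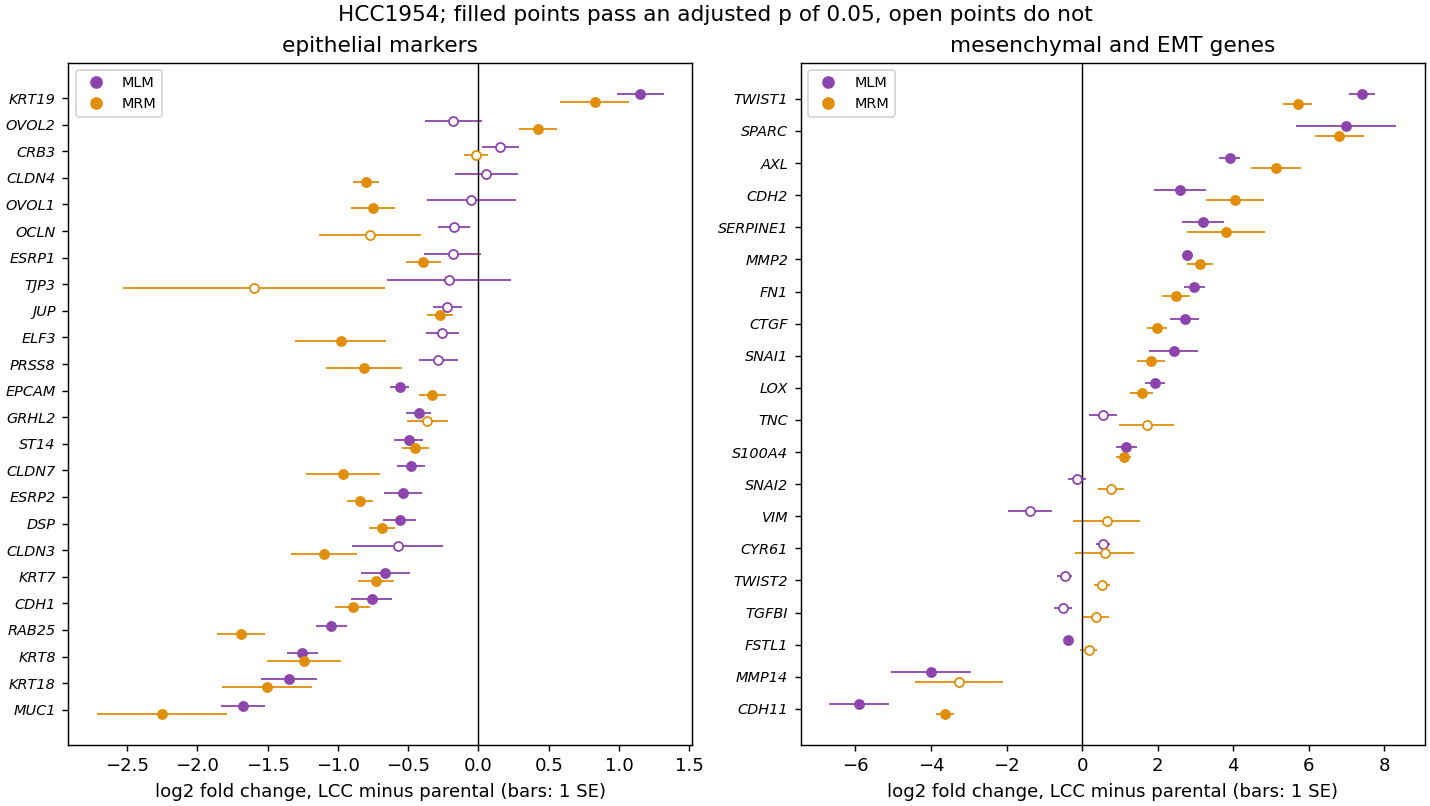
Log2 fold change of LCC against parental HCC1954 cells (± 1 SE) for epithelial markers and for mesenchymal and EMT genes, in MLM (purple) and MRM (orange), with filled points for adjusted p under 0.05. Epithelial markers lower in LCC cells number 12 of 24 in MLM and 18 of 24 in MRM.

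In MRM, HCC1954 LCC cells again held more FOXI1 (8.14 ± 0.82) and also more SPARC, a matricellular protein (6.81 ± 0.65), the receptor kinase ROS1 (6.08 ± 0.43) and the collagen chain COL6A2 (5.88 ± 0.33), with 4 against 3 libraries. LMAN1 was lower at -10.04 ± 0.42, MXRA5 at -6.91 ± 0.47, KRT4 at -6.15 ± 0.46 and CCL2 at -5.90 ± 0.37. Epithelial markers had 2 higher, 18 lower and 4 not called of 24 (2 and 19 adjusted over the list alone, camera adjusted p = 1.58e-04 with a preset correlation and adjusted p = 0.652 with an estimated correlation). RAB25 (-1.69 ± 0.17), CDH1 (-0.89 ± 0.13), the splicing regulator ESRP2 (-0.84 ± 0.09) and the tight junction protein CLDN4 (-0.80 ± 0.09) were lower. Mesenchymal and EMT genes stood at 11 higher, 1 lower and 8 not called of 20 (11 and 2 adjusted over the list alone, camera adjusted p = 0.0026 with a preset correlation and adjusted p = 0.925 with an estimated correlation). Markers of fibroblasts had 3 higher, 0 lower and 1 not called of 4 (3 and 0 adjusted over the list alone, camera adjusted p = 0.128). In MLM these had 2 higher, 0 lower and 2 not called of 4 (2 and 0 adjusted over the list alone, camera adjusted p = 0.474). TWIST1 rose by 5.71 ± 0.38 and MMP2 by 3.12 ± 0.35, while the cadherin CDH11 was lower at -3.63 ± 0.24. ERBB2 and breast identity genes gave 3 higher, 7 lower and 8 not called of 18 (3 and 7 adjusted over the list alone, camera adjusted p = 0.407). ERBB2 itself was not called (-0.43 ± 0.18, adjusted p = 0.0941).

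WNT target genes of HCC1954 in MRM held 7 higher, 1 lower and 6 not called of 14 (7 and 1 adjusted over the list alone, camera adjusted p = 0.474). The transcription factors LEF1 (4.45 ± 0.48) and TCF7 (2.40 ± 0.48) were higher. WNT inhibitors had 3 higher, 1 lower and 2 not called of 6 (3 and 1 adjusted over the list alone, camera adjusted p = 0.695). DKK1 rose by 1.71 ± 0.51 (adjusted p = 0.0328). Cell cycle genes counted 8 higher, 9 lower and 23 not called of 40 (8 and 12 adjusted over the list alone, camera adjusted p = 0.907). The replication helicase subunit MCM3 (0.88 ± 0.08) and the cyclin CCNA2 (0.69 ± 0.09) were higher and the kinesin KIF20A was lower (-0.74 ± 0.08). Of cell cycle genes 34 of 40 stood higher both in LCC1 library 2 than in library 1 and in parental 3 of MLM than in the other parental libraries. CDKN1A, an inhibitor of cyclin-dependent kinases, rose by 1.03 ± 0.13. Its list, CDK inhibitors and quiescence, gave 5 higher, 6 lower and 13 not called of 24 (5 and 6 adjusted over the list alone, camera adjusted p = 0.7). Glycolysis and hypoxia genes showed 1 higher, 8 lower and 20 not called of 29 (1 and 8 adjusted over the list alone, camera adjusted p = 0.172). The hexokinase HK2 was lower at -1.11 ± 0.08 and PFKFB3, a regulator of glycolysis, at -1.97 ± 0.19, the latter within the run of neighbouring genes that starts at NET1 (median -0.91). MHC class I and antigen processing had 3 higher, 8 lower and 9 not called of 20 (3 and 8 adjusted over the list alone, camera adjusted p = 0.549). The peptide-trimming ERAP2 (-1.49 ± 0.17) and the chaperone CALR (-0.71 ± 0.11) were lower. LCC1 library 2 lay below library 1 by a median of -0.83 in this list and -2.04 in interferon stimulated genes. The interferon list had 2 higher, 4 lower and 29 not called of 35 (0 and 1 adjusted over the list alone, camera adjusted p = 0.695). SOX factors stood at 4 higher, 5 lower and 14 not called of 23 (4 and 5 adjusted over the list alone, camera adjusted p = 0.698). SOX9 stood at 0.74 ± 0.09, SOX2 at -3.33 ± 0.48 and SOX4 at -1.86 ± 0.29, the last in a run of genes from KDM1B to HIST1H1C (median -0.73). MKI67 was not called (-0.06 ± 0.16, adjusted p = 0.793).

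In HCC1954 in MRM, limma called 2959 genes higher and 2973 lower of 15432, with 51.6% of genes not overlapping, and 5905 genes were called with libraries of a derivative averaged. Scaling to the library total, which moved the median by 0.12, gave 3807 and 2146. The 5932 calls became 3669, 3681 and 3729 without parental 1, 2 and 3, and 7431 without LCC1 library 2.

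Few HCC1954 genes had an LCC effect that differed between the media. FGB, a fibrinogen chain, differed by 2.68 ± 0.36 (MLM minus MRM, adjusted p = 0.0258) and the stress gene GADD45B by 0.89 ± 0.14, against -1.68 ± 0.26 for the sulfotransferase CHST10 and -0.97 ± 0.14 for FBXO32, a ubiquitin ligase subunit. camera called 8 of 31 lists, lower in MLM for WNT ligands and receptors (0 members called, adjusted p = 0.00355) and higher for interferon stimulated genes (0 called, adjusted p = 0.00202). In 33 of 35 interferon genes both libraries that stood apart lay lower, by a median of -1.08 in parental 3 of MLM and -2.04 in LCC1 library 2 of MRM, and both raise this difference. The lowest of the 31 was adjusted p = 0.109 with an estimated correlation. The 24 limma calls (10 higher and 14 lower of 15397, with 1540 at an unadjusted p under 0.05) became 116 with libraries of the same name paired as a block, though LCC1 library 2 of MLM matched library 1 of MRM best, and 187 without parental 3 of MLM and LCC1 library 2 of MRM. They became 0 without parental 1, 2 or 3 or LCC2 library 2 of MRM, or without parental 1 or LCC1 library 2 of MLM, 1 without LCC2 library 1 of MRM, and 43 and 50 without LCC1 library 1 and 2 of MRM. Without a library of MLM they became 2 for parental 2, 4 for LCC1 library 1, and 6 and 9 for LCC2 library 1 and 2.

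The HCC1954 derivatives differed from each other. RPS6KA2, an S6 kinase family member, stood at a mean of 2596 normalized counts in LCC2 and 9.24 in LCC1 in MLM (8.01 ± 0.19, 2 against 2 libraries). COL17A1, a hemidesmosome collagen, was lower in LCC2 at -4.30 ± 0.11. LARP6, an RNA-binding protein, was read 0 times in LCC2 and had a mean of 480.1 in LCC1. In MRM the glucose transporter SLC5A1 was higher in LCC2, 443.5-fold, with a 95% counting interval of 151.5 to 2153 (3 reads in LCC1), and the keratin KRT6A (-3.29 ± 0.09) and the metallothionein MT2A (-3.15 ± 0.10) were lower. limma called 2935 genes higher and 3090 lower in LCC2 in MLM, and 2534 and 2867 in MRM. With library totals, which moved the median by 0.14 and 0.16, these were 4238 and 2138, and 3852 and 1943. Against the parental cells in MLM, 2471 genes were higher and 2732 lower in both derivatives and 427 went opposite ways, and in MRM 2647, 2715 and 385. The fold changes of both correlated across genes at 0.715 and 0.746, against 0.401 and 0.403 simulated for unchanged groups sharing the controls. The covariance of 0.872 and 0.894 exceeded the simulated one by 0.85 and 0.873. Against different parental libraries, 1 for a derivative and 2 for the other, the 6 possible ways gave 0.519 to 0.734 in MLM and 0.72 to 0.735 in MRM. Part of the overlap of calls may come from the shared controls. The 6025 calls in MLM became 9667 without parental 3, 3031 and 2683 without LCC1 library 1 and 2, and 2662 and 2695 without LCC2 library 1 and 2. The 5401 in MRM became 10005 and 9085 without LCC1 library 1 and 2, and 1778 and 1920 without LCC2 library 1 and 2.

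Across lines and media, 15 genes were higher and 17 lower in LCC cells in all 4 comparisons. SOX9 was higher by 0.96, 1.15, 0.81 and 0.74 in H2087 in MLM and MRM and HCC1954 in MLM and MRM. MCAM rose by 1.02, 0.78, 2.99 and 4.35 in the same order. Also higher were CAPS, a calcium-binding protein (from 0.88 to 2.73), and the growth factor PGF (from 1.46 to 2.69). COL8A1 was higher at 1.73 and 1.82 in H2087, 3.56 in HCC1954 in MRM and 22.6-fold, with a 95% counting interval of 7.51 to 111, in MLM. CCL2 was lower in all 4, as were the coactivator PPARGC1B (from -0.95 to -0.61), the histone demethylase KDM1B (from -0.94 to -0.66) and the interferon receptor IFNAR2 (from -1.10 to -0.51). Likewise lower were the lysosomal enzyme PPT1 (from -1.16 to -0.34), DEF6 (from -2.10 to -0.60) and UNC13B (from -0.70 to -0.35). Calls shared by both media of a line, if independent between the lines, would give 13.6 and 22.9 such genes of 11565 (Fisher's exact p = 0.385 and 0.933). PPT1 and, in MRM, KDM1B lie in runs of neighbouring genes that are lower in HCC1954 LCC cells.

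**Figure D3:**
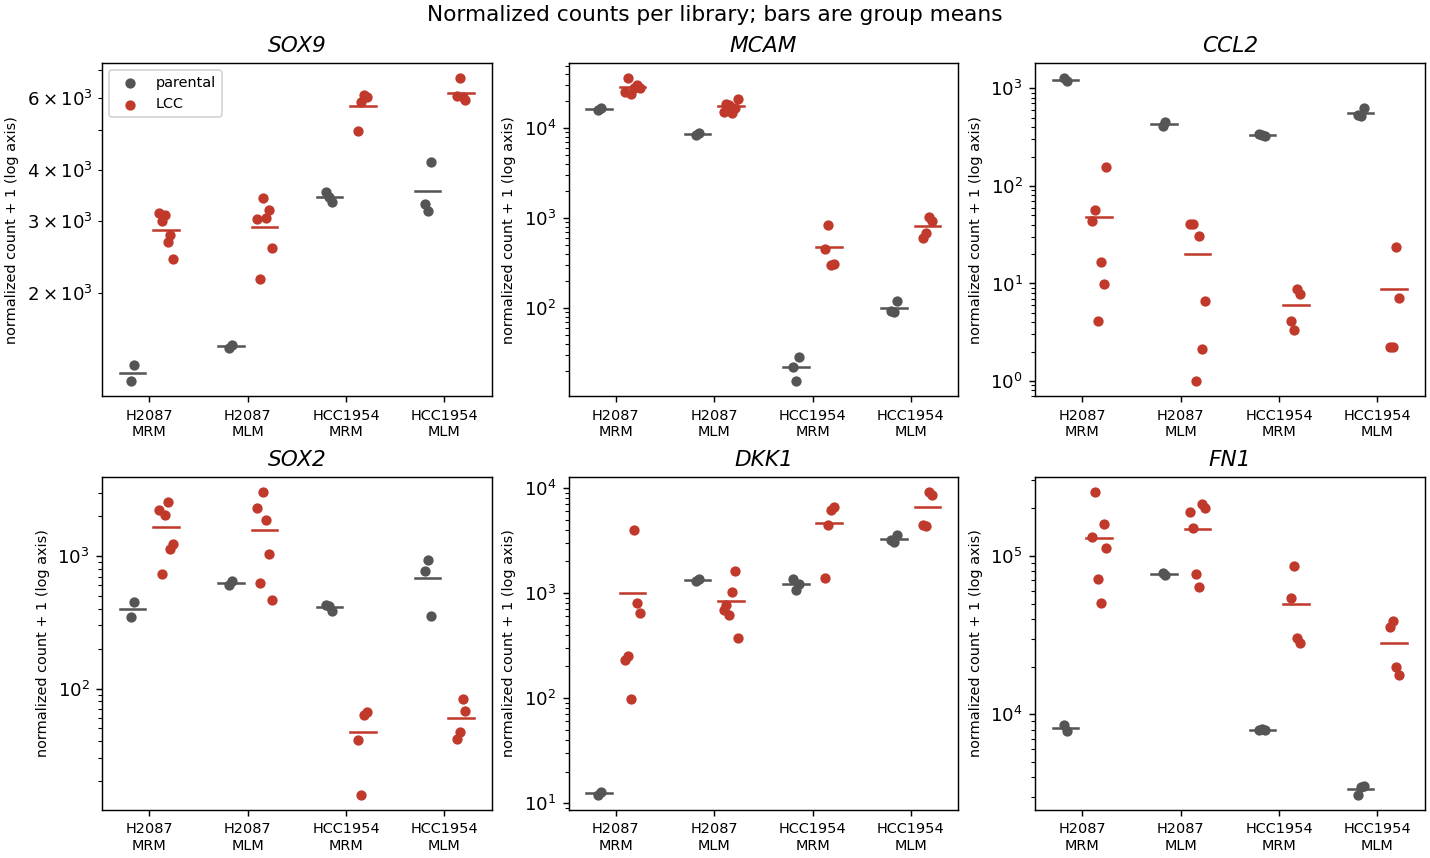
Normalized count plus 1 (log axis) of SOX9, MCAM, CCL2, SOX2, DKK1 and FN1 in each library, with bars at group means. SOX9 and MCAM are higher and CCL2 lower in every LCC library than in every parental library of the same line and medium.

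Between the lines, fewer LCC calls were shared than expected for independent lists, a deficit that was not tested. In MLM 83 genes were higher in both lines where 96.5 were expected and 174 lower where 223 were expected. In MRM the numbers were 152 and 116 against 183 and 151, with Fisher's exact adjusted p = 1 for each, one-sided for excess. More calls lay in opposite directions: genes higher in H2087 and lower in HCC1954 numbered 189 in MLM and 286 in MRM where 129 and 221 were expected, and the reverse 205 and 179 where 167 and 125 were. Limited to genes with an absolute log2 fold change of at least 1, the overlap exceeded the expected number, with 8 and 33 shared in MLM against 2.46 and 17.1 expected, and 48 and 18 in MRM against 23.6 and 11.8 (adjusted p = 0.00302, 0.000294, 2.86e-06 and 0.0473). Calls in opposite directions exceeded it as well, with 5 and 64 in MLM and 64 and 42 in MRM against 2.46, 17.1, 21.8 and 12.7 expected. The expected numbers of opposite calls were computed after the data were seen, and this excess was not tested. Fold changes of the lines correlated across genes at -0.077 in MLM and -0.087 in MRM, so the excess of shared calls does not show agreement between the lines. Within H2087, 124 genes were higher and 156 lower in both media, where 54.5 and 59.1 were expected. Within HCC1954 the numbers were 1888 and 1988, against 511 and 556, and SOX9, MCAM and CCL2 were among them in both lines. Fold changes correlated across genes at 0.257 between the media in H2087 and at 0.886 in HCC1954, and genes are not independent replicates.

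Between the media, H2087 libraries differed in genes of stress, MHC class I and NK ligand lists, while depth differed too and no list call was kept with an estimated correlation (lowest adjusted p = 0.455 in parental and 0.415 in LCC cells). HSPA5, the main chaperone of the endoplasmic reticulum, stood at 841 ± 7.72 CPM (SD, n = 2) in parental cells in MLM and 4666 ± 575 in MRM. The chaperone HSP90B1 was lower at -1.85 (log2, MLM minus MRM). Integrated stress and unfolded protein response genes had 0 higher, 18 lower and 8 not called of 26 (0 and 20 adjusted over the list alone, camera adjusted p = 3.76e-09 with a preset correlation and adjusted p = 0.565 with an estimated correlation) in parental cells. LCC cells (6 against 6 libraries) had 0 higher, 23 lower and 3 not called of 26 (0 and 25 adjusted over the list alone, camera adjusted p = 8.84e-12 with a preset correlation and adjusted p = 0.421 with an estimated correlation), and HSPA5 stood at -1.70. MHC class I genes had 1 higher, 13 lower and 6 not called of 20 (2 and 13 adjusted over the list alone, camera adjusted p = 1.84e-04 with a preset correlation and adjusted p = 0.677 with an estimated correlation) in parental cells. In LCC cells they had 2 higher, 13 lower and 5 not called of 20 (2 and 13 adjusted over the list alone, camera adjusted p = 4.93e-05 with a preset correlation and adjusted p = 0.421 with an estimated correlation). NK ligands counted 0 higher, 9 lower and 6 not called of 15 (1 and 10 adjusted over the list alone, camera adjusted p = 0.00166 with a preset correlation and adjusted p = 0.455 with an estimated correlation) in parental cells. LCC cells counted 0 higher, 10 lower and 5 not called of 15 (0 and 10 adjusted over the list alone, camera adjusted p = 0.00156 with a preset correlation and adjusted p = 0.415 with an estimated correlation). ULBP2 was lower at -2.06 in parental and -0.70 in LCC cells. Heat shock genes gave 13 higher, 0 lower and 4 not called of 17 (14 and 0 adjusted over the list alone, camera adjusted p = 3.57e-05 with a preset correlation and adjusted p = 0.455 with an estimated correlation) in parental cells, with the chaperone HSPA8 at 1.23. Integrins and adhesion genes gave 1 higher, 10 lower and 15 not called of 26 (1 and 11 adjusted over the list alone, camera adjusted p = 0.0101 with a preset correlation and adjusted p = 0.677 with an estimated correlation) in parental cells. The same list gave 0 higher, 15 lower and 11 not called of 26 (0 and 15 adjusted over the list alone, camera adjusted p = 5.54e-04 with a preset correlation and adjusted p = 0.421 with an estimated correlation) in LCC cells, with ITGA3 at -0.75 in the latter. Cell cycle genes gave 20 higher, 0 lower and 20 not called of 40 (23 and 0 adjusted over the list alone, camera adjusted p = 0.00133 with a preset correlation and adjusted p = 0.677 with an estimated correlation) in parental cells. DKK1 stood at 48.9 ± 0.821 CPM in MLM and 0.399 ± 0.0181 in MRM in parental cells (adjusted p = 0.00861). In LCC cells it stood at 29.7 ± 15.2 and 32.2 ± 47 (adjusted p = 0.814). Notch pathway genes had 0 higher, 9 lower and 9 not called of 18 (0 and 9 adjusted over the list alone, camera adjusted p = 0.00741 with a preset correlation and adjusted p = 0.415 with an estimated correlation) in LCC cells. Lung identity genes had 0 higher, 8 lower and 5 not called of 13 (1 and 9 adjusted over the list alone, camera adjusted p = 0.012 with a preset correlation and adjusted p = 0.437 with an estimated correlation), with CEACAM6 at -1.72. edgeR called 2470 genes higher and 2259 lower in MLM in parental cells and 2140 and 2484 in LCC cells. The 4729 parental calls became 2706 without parental 1 of MRM and 2934 and 2896 without parental 1 and 2 of MLM. They include genes of 13 runs of neighbours that differ between these libraries, such as BUB1B and SNAI2.

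Between the media, HCC1954 libraries differed in genes of the cholesterol and cell cycle lists, while depth differed too and no list call was kept with an estimated correlation (lowest adjusted p = 0.102 in parental and 0.419 in LCC cells). HMGCS1, an early enzyme of cholesterol synthesis, stood at 1242 ± 226 against 361 ± 14.6 CPM (SD, n = 3) in parental cells. In LCC cells it stood at 810.3 ± 156 against 267 ± 74.2 (n = 4). Cholesterol and fatty acid synthesis genes gave 26 higher, 0 lower and 7 not called of 33 (29 and 0 adjusted over the list alone, camera adjusted p = 2.79e-14 with a preset correlation and adjusted p = 0.22 with an estimated correlation) in parental cells. LCC cells gave 29 higher, 0 lower and 4 not called of 33 (30 and 0 adjusted over the list alone, camera adjusted p = 1.73e-19 with a preset correlation and adjusted p = 0.419 with an estimated correlation). The desaturase SCD rose by 1.72 in parental cells, and to 2174 ± 58.7 from 813 ± 431 CPM in LCC cells. Cell cycle genes had 1 higher, 15 lower and 24 not called of 40 (1 and 18 adjusted over the list alone, camera adjusted p = 3.40e-05 with a preset correlation and adjusted p = 0.913 with an estimated correlation) in parental cells. The LCC cells had 0 higher, 22 lower and 18 not called of 40 (0 and 25 adjusted over the list alone, camera adjusted p = 1.45e-12 with a preset correlation and adjusted p = 0.756 with an estimated correlation). The topoisomerase TOP2A was lower at -0.72 and -1.10, and MKI67 in LCC cells at -0.90. The libraries that stood apart, parental 3 of MLM and LCC1 library 2 of MRM, both lay lower than the other libraries of their kind in 27 of 33 cholesterol genes and both higher in 34 of 40 cell cycle genes. WNT ligands and receptors held 10 higher, 0 lower and 17 not called of 27 (14 and 1 adjusted over the list alone, camera adjusted p = 5.11e-04 with a preset correlation and adjusted p = 0.102 with an estimated correlation) in parental cells. WLS rose there by 0.96, and DKK1 rose by 1.39. Interferon stimulated genes had 2 higher, 0 lower and 33 not called of 35 (0 and 0 adjusted over the list alone, camera adjusted p = 4.30e-04 with a preset correlation and adjusted p = 0.945 with an estimated correlation) in LCC cells. Of 35 such genes 33 lay lower in both libraries that stood apart. Stress response genes gave 15 higher, 0 lower and 11 not called of 26 (20 and 0 adjusted over the list alone, camera adjusted p = 8.57e-08 with a preset correlation and adjusted p = 0.756 with an estimated correlation) in LCC cells. The amino acid transporter SLC7A5 stood at 0.62. Histone genes counted 6 higher, 0 lower and 5 not called of 11 (7 and 0 adjusted over the list alone, camera adjusted p = 0.0151 with a preset correlation and adjusted p = 0.756 with an estimated correlation) in LCC cells, HIST1H1C among them (1.12). LCC1 library 2 of MRM lay lower than library 1 by a median of -0.48 in the stress list and -0.73 in the histone list. edgeR called 1965 genes higher and 1815 lower in MLM in parental cells and 1703 and 1895 in LCC cells. The LCC calls became 3795 without LCC1 library 2 of MRM. The 3780 parental calls became 2315, 2259 and 1958 without parental 1, 2 and 3 of MRM, 2376 and 2134 without parental 1 and 2 of MLM, and 3456 without parental 3 of MLM.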

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

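The tests of the 3 patterns below and of other splits of the samples were chosen after the results were seen, while the differences of the LCC effect between the media were planned tests. In 22 of 238 groups of 4 or 6 LCC libraries, for genes named in the text, 1 library lay far from the rest. Chance gives about 1 in 20 groups, or 11.9, for independent libraries of normal spread. HCC1954 libraries come in pairs by derivative, LCC5 and LCC6 of H2087 in MRM were alike, and the genes were selected. The 11.9 thus need not hold for these groups. The numbers give the gap of the library that lay apart to its nearest neighbour, as a share of the group's range. Among H2087 LCC libraries in MLM stood LCC1 highest in QPRT (0.673), PPP2R2C (0.749) and WNT5B (0.644), LCC2 highest in PPARGC1B (0.646), LCC2 lowest in FGF1 (0.704) and ETV5 (0.654), LCC4 lowest in BMP6 (0.650) and LCC6 highest in MYC (0.651). For H2087 in MRM these were LCC2 lowest in DNAJB1 (0.655), LCC4 highest in KRT7 (0.765), LCC4 lowest in ADAMTS4 (0.803) and LCC6 lowest in ZSCAN18 (0.654). HCC1954 in MLM had LCC1 library 2 highest in LMAN1 (1, a share fixed by the only read among these libraries) and SOX9 (0.835), and in MRM LCC1 library 1 highest in PFKFB3 (0.917) and COL1A1 (0.847), LCC1 library 1 lowest in KRT13 (0.906), LCC1 library 2 highest in TAGLN (0.856) and LCC1 library 2 lowest in DEF6 (0.921), SCD (0.985), TNFSF10 (0.908) and ACTA2 (0.840).

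Named genes whose LCC effect differed between the media by limma (log2, MLM minus MRM, in H2087 without a block) were, on the positive side, ADAMTS4 7.34, UNC5B 4.19, SH3TC1 2.34, CSF2 2.15, ULBP2 1.38, KIF13B 1.34, CTGF 1.30, ICAM1 0.90, RBL2 0.89 and HSP90B1 0.78. Negative were ELOVL2 -8.83, QPRT -8.43, BMP7 -7.81, SEMA3C -7.16, MME -6.62, CRISPLD1 -6.36, WNT5B -6.34, DKK1 -6.07, PPP2R2C -5.42, ZSCAN18 -4.78, CMBL -4.28, BMP6 -4.13, GRIK2 -3.80 and BMP4 -3.35. The same holds for FN1 -2.99, BIRC3 -2.91, TGFB2 -2.78, SOX4 -2.69, SOX21 -2.41, HMOX1 -1.90, SFN -1.85, BAG4 -1.64, HES6 -1.53, VDAC3 -1.44, TXNIP -1.39, FOSL1 -1.14, CCND1 -1.06 and CDC6 -0.79. Smaller negative differences were those of IFNAR2 -0.50. In HCC1954 the named genes were FGB 2.68, GADD45B 0.89, CHST10 -1.68 and FBXO32 -0.97. Values of genes with 1 to 3 reads in a group, such as MME and GRIK2, depend on the pseudocount.

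For some named genes every LCC library of 1 line lay above its parental libraries and every LCC library of the other line below. The difference between the lines was not tested. In MLM the LCC effect in H2087 exceeded that in HCC1954 for CCNG2 2.76 and KRT8 1.75 (log2), and it was smaller for BMP7 -9.05, PPP2R2C -8.83, QPRT -8.43, BMP6 -8.38, IL6 -5.05, HMOX1 -2.62, NFKB2 -2.20 and CHST10 -1.77. In MRM it was larger for KRT4 10.10, KRT6A 8.14, CEACAM6 7.01, BMP4 6.17, SOX2 5.27, CMBL 5.17, NOTCH3 5.09, SOX4 4.88, TNFSF10 4.31, CORO1A 2.73, SFN 2.47, GADD45B 2.27, KRT7 2.08, DSC2 1.68, CLDN4 1.62, DNAJB1 1.33, HMGCS1 1.31, SCD 1.27, BUB1B 1.14, NQO1 0.94 and CCNB2 0.81. Smaller values in H2087 belonged to SPARC -7.53, ADAMTS4 -7.14, RRAGD -6.03, BCL2 -5.29, ACTA2 -4.87, CHST10 -3.13 and TAGLN -2.72. LCC1 library 2 of HCC1954 in MRM, far below the other LCC libraries in SCD, TNFSF10 and ACTA2, widens the first differences and narrows that of ACTA2. In TAGLN it lay far above, which widens the difference.

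The H2087 parental libraries differ between MLM and MRM in 13 runs of neighbouring genes that hold 301 of 11175 placed genes, where the highest of 100 permuted gene orders gave 14. A response to the medium shared by both cell types is argued against: the same genes had a median shift of 0.772 in parental libraries and of 0.103 in LCC libraries, with quartiles of -0.13 and 0.30. As medians from the level of all H2087 libraries, the MLM parental libraries stood at 0.71 and 0.69 in the run from TTI2 to LYPLA1. In the run from MRPL36 to PAIP1 the MRM parental libraries stood at -0.84 and -0.79, and LCC6 of MLM at -0.70. Another subline or a wrong label among the parental libraries of 1 medium, or of both, stays open. It rests on the 301 genes themselves, as no DNA was measured and each medium has 2 parental libraries. A response of parental cells alone was not tested.

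In HCC1954 the LCC and parental libraries differ in 39 runs holding 1147 of 12578 placed genes in MLM and in 42 runs holding 1107 in MRM. A shift of the MLM libraries alone is argued against, since 38 of the 39 runs found in MLM had the same sign in MRM. A copy number that differs between the derivatives and the parental line may explain such runs, and 26 of them also passed the threshold in MRM with the same sign. The same derivatives were grown in both media, so this repeat does not show runs common to LCC cells. Of 53 runs of LCC1 against parental libraries in MLM, 36 passed the threshold the same way in LCC1 of MRM and 14 in LCC2 of MRM. No DNA was measured, so a difference in copy number stays open, as does a shared regulation of neighbouring genes, which was not tested.

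HCC1954 parental 3 in MLM and LCC1 library 2 in MRM stand apart from their groups, with 481 and 884 genes more than 2-fold away. The deviations of both held 0 genes in runs, so neither showed the runs seen between LCC and parental libraries of HCC1954. This cannot exclude a library of another subline. Derivatives can differ without such runs, since H2087 LCC1 and LCC3 in MLM also held 0 genes in runs against the other derivatives. A culture or preparation state shared by these libraries may be a cause: their deviations correlate across genes at 0.582 (Spearman 0.556). The labels name no batch and no biological explanation was tested, so the source stays open.

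Other splits of the samples were counted for groups of at least 3. For HCC1954 in MLM 1 of 35 splits gave as many calls, the real one with 5541, and the highest other gave 275. In MRM it was 1 of 35 as well, with 5932 against 523. Chance would be excluded only if the 4 LCC libraries, 2 from each derivative, were exchangeable, and they were not. In MLM libraries of 1 derivative differed by a chi-square per degree of freedom of 3.64 and 2.85, and those of different derivatives by 106 to 125. In MRM these were 115 and 2.10, against 113 to 229. The 35 splits thus cannot exclude chance in either medium. With libraries of a derivative averaged, 10 splits are too few for a share under 0.05, and gave 2593 against 0 in MLM and 5905 against 0 in MRM. For H2087 LCC libraries between media 1 of 100 splits gave as many, 4624 against 1513. Of the 32 splits that part all 6 pairs the highest other gave 0. Chance is excluded only if the 6 pairs are distinct derivatives, which is in doubt for LCC5 and LCC6 of MRM. With fewer pairs the splits may be too few for a share under 0.05. For the HCC1954 difference of the LCC effect 2 of 100 did, the real one with 24 and another with 552, along the derivatives. That split points to a structure of the samples, and the real count ran from 0 to 50 with 1 library left out, so it is left open whether chance gave it. HCC1954 LCC libraries between media had 2 of 35, the real one with 3598 and the split of LCC1 from LCC2 with 5631, which parts no pair and shows the derivatives as a structure. Of the splits that part all 4 pairs of the same name, 8 are too few for a share under 0.05, and the highest other gave 0. With LCC libraries of the same name as a block the count was 4364. For HCC1954 parental libraries between media, 10 splits are too few for a share under 0.05, and 1 of them, the real one, gave 3780 while the highest other gave 0.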

How the results depend on the processing

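The alternatives leaving out LCC6, leaving out both HCC1954 libraries that stood apart, and all those for calls between media were chosen after the data were seen, and the others before the data were examined. Over named genes and lists under all alternatives, 15537 values kept their side of the threshold, 958 lost and 232 gained a call. Another 7 reversed their direction with a call before or after. A change of direction without any call was counted among the 15537, as for VIM in HCC1954 in MRM (0.65, and -0.26 without LCC1 library 2). Of counts of calls 181 stayed within 1.5 times the reported count, 33 rose and 52 fell beyond it, and 59 level ratios moved by less than the spread between replicates and 9 by more. Where a value below left that range, the cause was not tested unless stated.

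In H2087 the 1711 calls in MLM became 2725 with DESeq2 and 6132 with weights per library, and the 1822 in MRM 2753 and 5253, or 2783 with a spread shared over both media. In HCC1954 the 5541 calls in MLM became 8823 with 3 group means, 8465 with LCC1 alone, and 2593 with derivatives averaged, which leaves fewer samples. Weights gave 11928 in MRM in place of 5932, and their estimate stopped before convergence in MLM. Libraries of the same number within 1 HCC1954 table correlated at -0.08 to 0.05 and do not pair. A block by that number gave 3602 calls in MLM and 2310 in MRM, and for LCC2 against LCC1 9535 and 2889 in place of 6025 and 5401.

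With same-named libraries as a block, the difference of the LCC effect between media had 3426 calls in H2087 in place of 1344 and 116 in HCC1954 in place of 24. Only LCC libraries pair by that block, in HCC1954 3 of 4 by name. The HCC1954 count was 10 at a pseudocount of 0.5, 13 without a filter, 12 with edgeR, 308 with DESeq2 and 187 without both libraries that stood apart. The H2087 count was 1357 without LCC6. Between media the same block gave 9491 calls in place of 4729 in H2087 parental libraries and 6460 in place of 3780 in HCC1954 ones, which do not pair.

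Lists called by camera numbered 4, 2, 1 and 2 for H2087 in MLM and MRM and HCC1954 in MLM and MRM, and 0 in each with an estimated correlation. fry called 5 in H2087 in MRM and 7 and 11 in HCC1954, and the library total gave 4 in H2087 in MRM. Calls shared between the lines went from below to above the expected number at an absolute log2 fold change of at least 1, with 8 and 33 in MLM and 48 and 18 in MRM, while opposite calls lay above it at either threshold, here with 5 and 64 and with 64 and 42. In HCC1954 in MRM weights per library reversed AXIN2 (0.57), MICB (-0.97), CDKN1B (0.18) and VIM (-0.43), and LCC2 alone reversed AXIN2 (0.61) and MICB (-1.02), reported at -0.48, 0.03, -0.07 and 0.65. CYR61 between media in HCC1954 LCC libraries (-0.08) ran from -0.40 to 1.08 with 1 library left out, the highest without LCC1 library 2 of MRM.

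With 1 library left out at a time, calls ran from 113 to 2448 and 141 to 2288 in H2087 in MLM and MRM, and from 3660 to 5190 and 3669 to 7431 in HCC1954. A lone parental library of H2087 is assumed to vary like the other groups. The difference between media ran from 409 to 1633 in H2087 and 0 to 50 in HCC1954, and LCC2 against LCC1 from 2662 to 9667 in MLM and 1778 to 10005 in MRM. Calls between media ran from 2706 to 3416 and 4114 to 4881 in H2087 parental and LCC libraries, and from 1958 to 3456 and 2749 to 3953 in HCC1954. Called lists ran from 3 to 7, 1 to 5, 1 to 3 and 2 to 6 in the order above. Single genes of the text that moved by over 1.5 times include CRISPLD1 (3.98 to 6.85 in H2087 in MRM, not called without parental 2), KCNJ12 (-5.79 there without LCC4), ZDHHC2 (7.16 in HCC1954 in MLM without parental 1), CCL2 (-7.41 there without LCC2 library 1) and, in HCC1954 in MRM without LCC1 library 2, FOXI1 (8.82) and TNFSF10 (-2.23). Depth limits genes with few reads, given with counting intervals.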

Other observations

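The lists not given above were tested in the same way, and the counts of pseudogenes and of lists with differing signs were made after the data were seen. Death receptors and apoptosis ligands of HCC1954 in MRM had 2 higher, 4 lower and 10 not called of 16 (2 and 4 adjusted over the list alone, camera adjusted p = 0.652). The apoptosis factor BID stood at -1.05 ± 0.11, the survival factor BCL2 at 4.33 ± 0.42 and the death ligand TNFSF10 at -3.05 ± 0.81. Basal and squamous keratins had 4 higher, 8 lower and 13 not called of 25 (5 and 8 adjusted over the list alone, camera adjusted p = 0.549), with the keratins KRT13 at -2.66 ± 0.32 and KRT14 at -1.72 ± 0.33 and the calcium-binding S100A7 at -3.45 ± 0.50. In H2087 in MRM the same list had 4 higher, 0 lower and 10 not called of 14 (4 and 0 adjusted over the list alone, camera adjusted p = 0.237). The regulator SFN rose there by 1.71 ± 0.11 and the desmosome cadherin DSC2 by 1.12 ± 0.22.

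In HCC1954 in MRM more mesenchymal and EMT genes were called higher than lower, a list call not kept with an estimated correlation. Fibroblast markers higher in the same comparison were ACTA2, an actin of smooth muscle, at 3.96 ± 0.30, TAGLN at 2.01 ± 0.54 and the collagen chain COL1A1 at 0.67 ± 0.16. Blood and immune cell markers had 4 higher, 2 lower and 2 not called of 8 (4 and 2 adjusted over the list alone, camera adjusted p = 0.57), CSF1R at 2.14 ± 0.31 and CORO1A at -1.72 ± 0.25. Endothelial markers had 1 higher, 0 lower and 7 not called of 8 (1 and 0 adjusted over the list alone, camera adjusted p = 0.57). Kidney markers had 3 higher, 1 lower and 2 not called of 6 (3 and 1 adjusted over the list alone, camera adjusted p = 0.549), CDH16 at 3.62 ± 0.85 and PAX2 at 2.93 ± 0.59. Ribosomal proteins gave 0 higher, 7 lower and 29 not called of 36 (0 and 1 adjusted over the list alone, camera adjusted p = 0.695). In H2087 in MLM ribosomal proteins had 0 higher, 3 lower and 33 not called of 36 (0 and 1 adjusted over the list alone, camera adjusted p = 0.745).

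Between MLM and MRM in HCC1954, 375 tested pseudogenes had a median log2 change of -0.32 in parental and -0.18 in LCC libraries, against 0.03 and 0.01 for protein-coding genes. Called lower in MLM were 80 and 65 of them, against 1478 and 1634 of 13647 protein-coding genes. Called higher were 33 and 31, against 1860 and 1595. Their changes in both cell types correlated at 0.881 (Spearman 0.770), against 0.62 (Spearman 0.664) for protein-coding genes. In 10, 4, 7 and 5 of 31 lists (H2087 in MLM and MRM, HCC1954 in MLM and MRM) the median, the mean and the list test differed in sign, and camera called 0 of them.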
